A study of Mus musculus with 10 samples.

How the data were processed

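Liver RNA of 10 female HET3 mice (a genetically heterogeneous stock bred by crossing inbred strains) was profiled by poly-A selected bulk RNA sequencing, with 5 mice on a standard diet and 5 on the Longevity diet. Library strandedness is not stated per sample, and the labels give no sequencing batch, cage or time of collection. Each mouse is named by its title, such as LD_405, where SD stands for standard diet and LD for Longevity diet. No mouse number occurs on both diets, and the comparison was made unpaired. Whether mice were matched between the diets, as by cage or cohort, is not known.

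The deposited table holds 1 column per mouse and 19414 genes, 14821 of them protein-coding. Its values are CPM, counts per 1e+06 reads on the listed genes, to which the authors added 0.0001. All columns have the same total before that addition, and low values rise in steps of 1 size per library that do not depend on gene length. STAR, Partek and the mm39 mouse genome are named in the labels without versions, and the quantifier, annotation release and low-count filter are not stated. The added 0.0001 was subtracted before use. The step size of each column gave an estimated depth of 24.7 to 45.7 M reads (M, 1e+06 reads). Between 84.6% and 87.9% of the values under 100 reads lay within 0.1 of a whole read, which is under the 95% set for treating the values as counts. The estimated reads therefore served only for depth, for a floor of 3 reads per library, and for an added fit with weights. Reads are not independent molecules, so the floor covers counting error only. Coordinates are those of the deposited table on mm39, with the end taken as 1 below the printed stop. All 15 mitochondrial genes compared with GENCODE M21 showed that offset. GENCODE M21 (GRCm38) was used otherwise only for transcript length and GC content, which it gave for 97.1% of the genes in the table.

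Values were analysed as log2(CPM + 0.1) for the 13157 genes with a mean of at least 1 CPM over the 10 mice. The diets were compared with limma 3.58.1 (trend and robust empirical Bayes, statmod 1.5.0, R 4.3.3), diet being the only term, with two-sided tests and the Benjamini-Hochberg adjustment at 0.05. A gene is said to have risen, fallen or changed when it passed that threshold. Fold changes are Longevity diet over standard diet, and each adjusted p given for a gene comes from limma. The approach was tested on simulated data with the same layout, in 5 simulations of 200 changed genes each and 13115 to 13195 genes tested. It recovered 2.42% of the genes simulated with a 1.5-fold change, 24.2% at 2-fold, 79.2% at 4-fold and 95.6% at 8-fold, and 4.55% of its calls were false. The simulated genes varied independently of each other, with no length or GC bias and no outlying library. These rates may therefore not hold for the real data.

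Before the data were examined, 46 gene lists for pathways, regulators and cell types were fixed. Of their 884 entries, 851 were found in the table, and 43 lists had at least 3 measured members. They were tested with camera of limma at a preset correlation between genes of 0.01, and repeated with an estimated correlation, with fry, and with an exact permutation test of a list score per mouse over the 252 assignments of 5 mice to a diet. The smallest two-sided p that this test can give is 0.00794. Members were also counted after adjustment over the list alone. Principal components were taken from all tested genes, and their scores and the library measures were compared by the same two-sided exact permutation test.

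The genes named were chosen by a rule fixed beforehand. It takes every measured gene of the list of FGF21, GLP-1 and their receptors. It takes the 10 genes with the largest rise and the 10 with the largest fall among changed genes whose 5 values on each diet did not overlap, leaving out predicted genes and pseudogenes. It also takes up to 4 members of each described list with the smallest p. Some genes that the rule takes are not reported here, and genes outside the rule are said to be so. The alternatives tried were other pseudocounts, filters, scalings and thresholds, weights per library, the leading digit of the mouse number (whose meaning, such as a cage or cohort, is not given) as a covariate, and leaving out each mouse in turn. A fit with weights per value by voom of limma, scaling without the most abundant genes, removal of length and GC slopes, and leaving out a pair of mice were added after seeing the data. Frailty, hormone levels and other measurements in the animals were not analysed here.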

Results

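Gene expression was measured in the livers of 10 female HET3 mice, 5 fed a standard diet and 5 fed the Longevity diet for 5 months. The labels give an age of 25 months, without settling whether this was the age at the start or at the end of the feeding. The estimated depth was 42.5 ± 4.35 M reads per library (M, 1e+06) on the standard diet and 30.0 ± 6.47 M on the Longevity diet (mean ± SD, n = 5 mice each, exact permutation p = 0.0159). The lowest depth was 24.7 M reads, at which 3 reads correspond to 0.121 CPM. All values below are mean CPM ± SD of 5 mice per diet unless another measure is named, and positions are on mm39.

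The comparison asks how the liver transcriptome differs between mice on the Longevity diet and mice on the standard diet, with FGF21 and GLP-1 named in the title of the series. On the Longevity diet the liver held 9.77-fold more mRNA of the hormone Fgf21, and genes of fatty acid oxidation, lipid droplets, cholesterol synthesis and the ATF4 stress response stood higher as groups, while genes of amino acid breakdown and the urea cycle, the acute phase, extracellular matrix and several cell types other than hepatocytes stood lower as groups. These group calls were made by camera at its preset correlation, and 0 of the 18 lists called held with an estimated correlation (adjusted p = 0.0872 to 0.831 with an estimated correlation). Of 13157 genes tested, 249 changed, 87 of them higher and 162 lower on the Longevity diet, and 2309 had an unadjusted p under 0.05. The values of the diets did not overlap for 723 genes, or 5.50% of those tested, where chance gives 0.794%. The median log2 change over all genes was -0.11, and scaling by median-of-ratios, which moved that median by 0.110, gave 154 genes higher and 134 lower. Quantile normalization moved it by 0.114 and gave 151 higher and 148 lower.

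**Figure D1:**
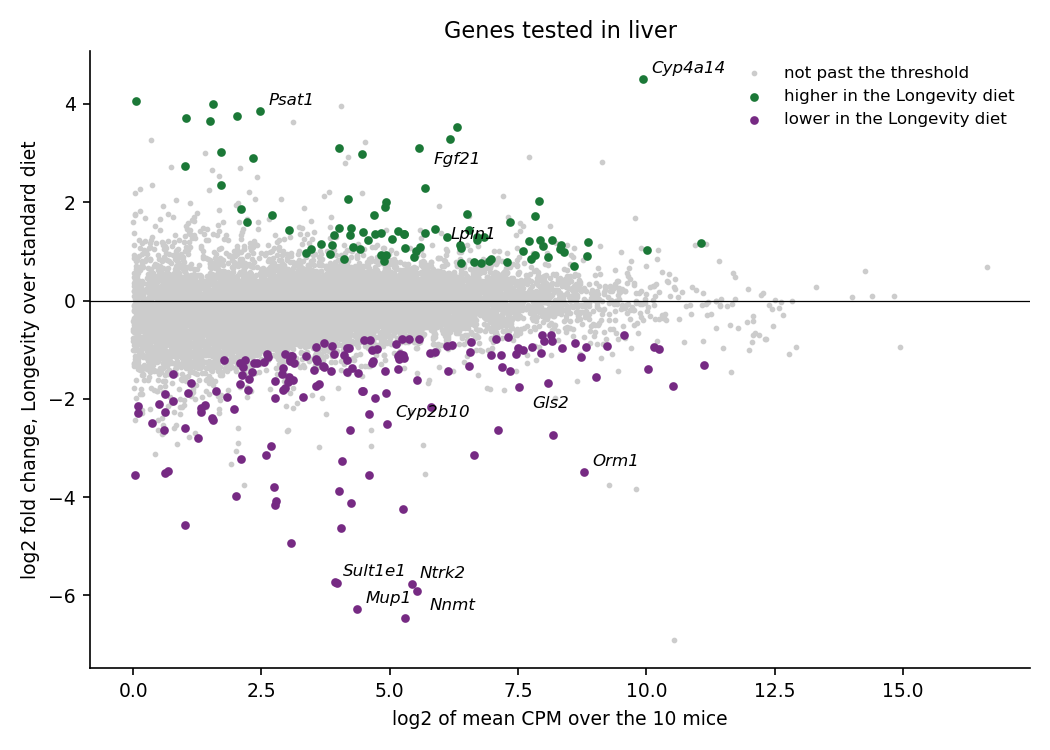
Log2 fold change, Longevity diet over standard diet, against mean expression of the 13157 genes tested, 1 point per gene. The 87 genes that rose are green and the 162 that fell are purple, and the largest falls exceed the largest rises.

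Fgf21 (ENSMUSG00000030827.6, chromosome 7 from 45263310 to 45264914, minus strand), a liver hormone released under nutrient stress, rose from 13.5 ± 6.73 to 131 ± 55.8 CPM. The log2 change was 3.29 (SE 0.43, 95% CI 2.37 to 4.21, adjusted p = 0.00356), a 9.77-fold rise. The 5 values on the standard diet lay between 5.33 and 21.2 CPM and the 5 on the Longevity diet between 47.8 and 178 CPM. The exact permutation p was 0.00794, the smallest the design allows. No other measured member of the list of FGF21, GLP-1 and their receptors changed. Klb, the co-receptor of FGF21, stood at 23.9 ± 8.58 and 34.0 ± 10.0 CPM (adjusted p = 0.371). Log2 differences were -0.46 for Fgfr1 (adjusted p = 0.487), 0.05 for Fgfr2 (adjusted p = 0.938), -0.47 for Fgfr3 (adjusted p = 0.380) and -0.41 for Fgfr4 (adjusted p = 0.237). Dpp4, which encodes a peptidase that inactivates GLP-1, was at 82.6 ± 5.45 and 60.5 ± 7.55 CPM (adjusted p = 0.149), and the glucagon receptor Gcgr at 248 ± 21.3 and 257 ± 62.5 CPM (adjusted p = 0.961). The signs for Gcgr and Fgfr2 turned under several settings. The GLP-1 receptor Glp1r averaged 0.147 and 0.162 CPM, under the filter. No entry was found among the 19414 genes for Gcg, which encodes the GLP-1 precursor. Of 8 measured members 1 rose and 0 fell, and 1 rose and 1 fell when adjusted over the list alone, Dpp4 being the latter. The median (-0.19) differed in sign from the mean (0.26) and the test, and camera gave an adjusted p of 0.828.

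**Figure D2:**
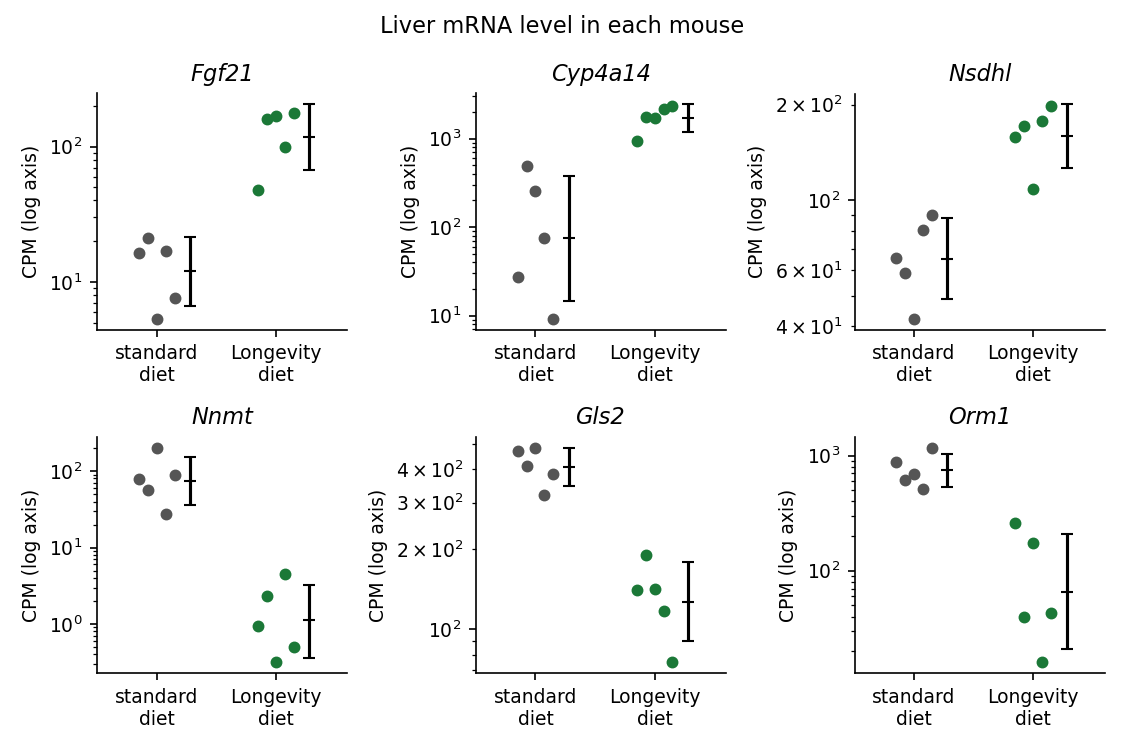
CPM on a log axis in each mouse for Fgf21, Cyp4a14, Nsdhl, Nnmt, Gls2 and Orm1, 1 point per mouse, with bars at the mean ± SD of the log2 values of 5 mice per diet. In each panel the 5 mice on the Longevity diet lie wholly above or wholly below the 5 on the standard diet.

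Fatty acid oxidation, ketogenesis and PPAR-alpha target genes stood higher on the Longevity diet. Of 30 measured members 7 rose and 0 fell (21 and 0 adjusted over the list alone), with a median log2 change of 0.75 and a camera adjusted p of 5.25e-21. That call did not hold with an estimated correlation (adjusted p = 0.160 with an estimated correlation). Pex11a, a peroxisome proliferation factor, rose from 61.1 ± 16.6 to 146 ± 14.5 CPM (log2 change 1.29, adjusted p = 0.00759). The mitochondrial acyl-CoA thioesterase Acot2 rose from 12.9 ± 6.47 to 47.9 ± 11.9 CPM (adjusted p = 0.0114). The beta-oxidation subunit gene Hadhb rose by 0.76 on the log2 scale (adjusted p = 0.0300), a call lost in 8 of 24 alternative settings. The fatty acid omega-hydroxylase Cyp4a14 (chromosome 4 from 115343397 to 115353339) showed the largest log2 rise among the named genes with 0.1 CPM added. It went from 171 ± 202 to 1783 ± 539 CPM (log2 change 4.51, SE 0.95, adjusted p = 0.0446). Acot1, a cytosolic relative of Acot2, rose from 20.5 ± 19.8 to 138 ± 25.9 CPM (adjusted p = 0.0376). Cyp4a14 and Acot1 each lost the call in 10 of 24 alternative settings, with adjusted p up to 0.146 and 0.173 and log2 changes of 3.76 to 5.19 and 2.87 to 4.06, and reads of Acot1, Acot2 and Cyp4a14 can be shared with close paralogs.

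Lipid droplet and triglyceride storage genes also stood higher, with 3 of 19 measured members risen and 0 fallen (9 and 0 adjusted over the list alone), a median log2 change of 0.77 and a camera adjusted p of 6.15e-10 (adjusted p = 0.160 with an estimated correlation). The phosphatidate phosphatase Lpin1 rose from 42.1 ± 15.2 to 140 ± 32.0 CPM (log2 change 1.76, adjusted p = 0.00360). The triglyceride lipase Pnpla2 rose from 62.1 ± 11.1 to 147 ± 34.0 CPM (adjusted p = 0.00839). The lipid droplet coat protein gene Plin5 rose from 31.5 ± 9.41 to 85.7 ± 22.4 CPM (adjusted p = 0.0122). Pnpla2 encodes a lipase that breaks down stored triglyceride, although the list is named for storage.

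Of 24 measured genes of cholesterol synthesis 6 rose and 0 fell (12 and 0 adjusted over the list alone), with a median log2 change of 0.69 and a camera adjusted p of 2.00e-12 (adjusted p = 0.238 with an estimated correlation). The list score of LD_442 (-0.358) lay below those of SD_403 (-0.237), SD_502 (-0.0193) and SD_646 (-0.345). In the other mice of the Longevity diet it was 0.423 to 1.15. Nsdhl, an enzyme of sterol demethylation (chromosome X from 71962163 to 72002120), rose from 67.5 ± 18.6 to 162 ± 33.5 CPM (log2 change 1.29, SE 0.23, adjusted p = 0.0144), and Cyp51 and Idi1 rose by 1.23 (adjusted p = 0.0200) and 1.12 (adjusted p = 0.0253) on the log2 scale, with calls lost in 6 and 7 of 24 alternative settings. De novo lipogenesis gave a camera call towards higher values (median log2 change 0.36, 0.103 to 0.470 across settings, adjusted p = 0.000753, adjusted p = 0.558 with an estimated correlation). Its only changed member among 23 fell, however, and 2 rose and 1 fell when adjusted over the list alone. That member was the fatty acid desaturase Scd1, at 3256 ± 1794 and 1231 ± 307 CPM (log2 change -1.30, adjusted p = 0.0408), whose call was lost in 12 of 24 alternative settings. Tkfc, a kinase of fructose metabolism, stood at 232 ± 116 and 469 ± 47.9 CPM (adjusted p = 0.0506).

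Targets of ATF4 and the integrated stress response, a list that includes Fgf21, stood higher. Of 25 measured members 3 rose and 0 fell (10 and 0 adjusted over the list alone), with a median log2 change of 0.50 and a camera adjusted p of 1.58e-11 (adjusted p = 0.0872 with an estimated correlation). Besides Fgf21, the serine synthesis enzyme Psat1 rose from 0.715 ± 0.671 to 10.4 ± 5.23 CPM (log2 change 3.86, 2.65 to 4.65 across settings, adjusted p = 0.00630). Asparagine synthetase, Asns, rose from 0.448 ± 0.530 to 7.67 ± 4.57 CPM (log2 change 3.76, adjusted p = 0.0263), although LD_405 had 0.614 CPM. Across settings the log2 change of Asns ran from 2.35 to 4.96, and the call was lost in 8 of 23 (adjusted p up to 0.152). Nupr1, a stress-induced transcription regulator, was at 1.68 ± 1.17 and 7.89 ± 5.00 CPM (adjusted p = 0.0559).

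Genes of amino acid catabolism and the urea cycle stood lower. Of 28 measured members 7 fell and 0 rose (16 and 0 adjusted over the list alone), with a median log2 change of -0.72 and a camera adjusted p of 5.10e-09 (adjusted p = 0.160 with an estimated correlation). The liver glutaminase Gls2 (chromosome 10 from 128030326 to 128045873) fell from 413 ± 65.7 to 133 ± 41.7 CPM (log2 change -1.69, SE 0.23, adjusted p = 0.00394). Aass, the first enzyme of lysine breakdown, fell from 207 ± 28.9 to 84.1 ± 27.9 CPM (adjusted p = 0.0114). The urea cycle enzyme Otc fell from 367 ± 29.7 to 208 ± 17.4 CPM (adjusted p = 0.0128), and the mitochondrial ornithine carrier Slc25a15 from 260 ± 52.7 to 128 ± 18.6 CPM (adjusted p = 0.0141).

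The methionine cycle and transsulfuration list was not called as a group (camera adjusted p = 0.363), with 1 of 27 measured members risen and 2 fallen (2 and 3 adjusted over the list alone). Nicotinamide N-methyltransferase, Nnmt (chromosome 9 from 48503177 to 48516453), which uses S-adenosylmethionine to methylate nicotinamide, fell from 91.0 ± 66.3 to 1.72 ± 1.75 CPM. This was a log2 change of -5.91 (SE 0.64, adjusted p = 0.00160), or 60.2-fold, and ran from -6.39 to -5.01 across settings. Bhmt, which remethylates homocysteine to methionine, fell from 1476 ± 147 to 627 ± 280 CPM (adjusted p = 0.0438). Glutathione synthetase, Gss, rose by 0.79 on the log2 scale (adjusted p = 0.0422). The calls of Bhmt and Gss were each lost in 11 of 24 alternative settings, with adjusted p up to 0.170 and 0.152.

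**Figure D3:**
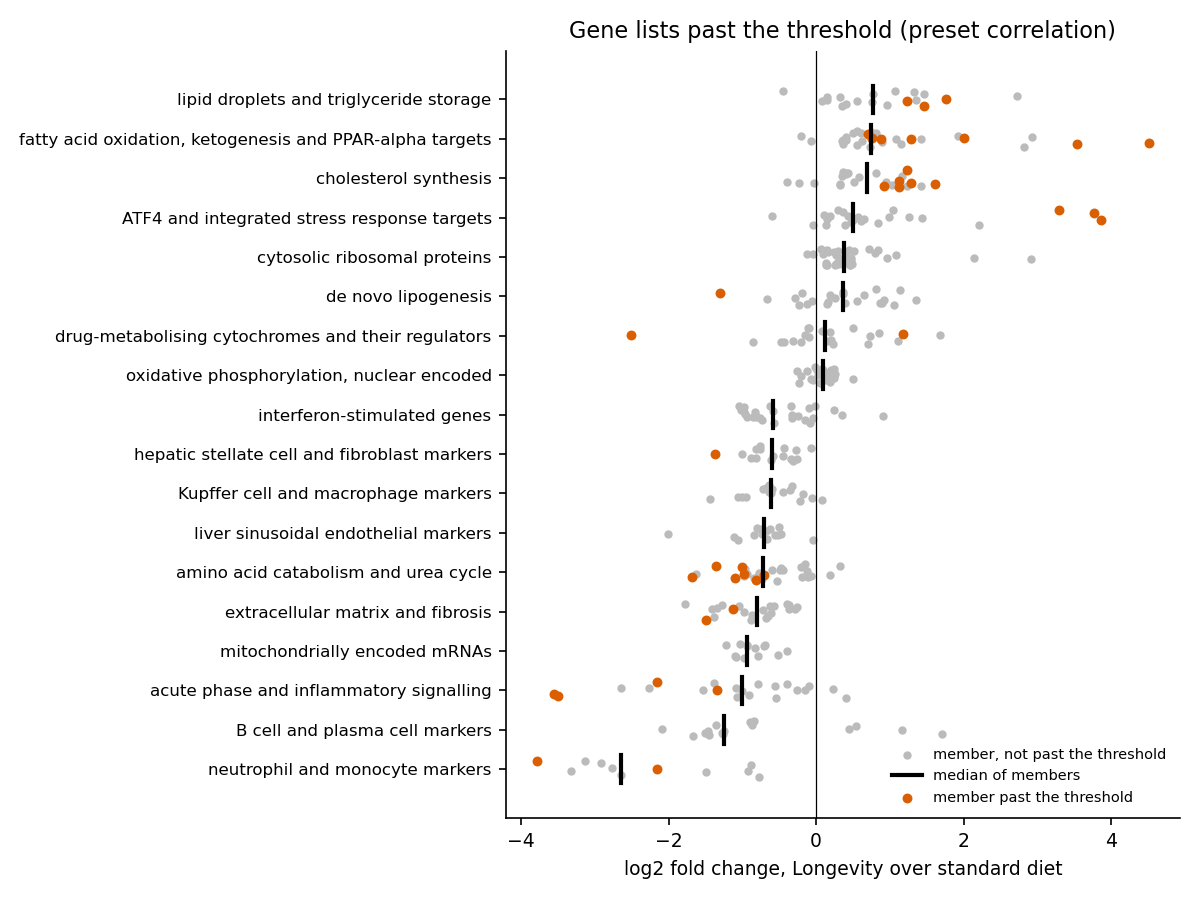
Log2 fold change, Longevity diet over standard diet, of each measured member of the 18 gene lists called by camera, 1 point per gene, with members past the threshold in orange and the list median in black. Medians run from -2.64 in neutrophil and monocyte markers to 0.77 in lipid droplets and triglyceride storage.

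Acute phase and inflammatory genes stood lower. Of 21 measured members 4 fell and 0 rose (7 and 0 adjusted over the list alone), with a median log2 change of -1.01 and a camera adjusted p of 6.06e-05 (adjusted p = 0.439 with an estimated correlation). The list scores of LD_442 (0.0966) and LD_513 (0.324) lay above that of SD_502 (-0.0365). Scores were -0.944 to -0.712 in the other mice of the Longevity diet and 0.421 to 0.646 in the other standard diet mice. The plasma glycoprotein genes Orm1 and Orm2, whose reads can be shared with each other, fell from 775 ± 259 to 107 ± 106 CPM (adjusted p = 0.0216) and from 44.0 ± 22.7 to 4.11 ± 2.92 CPM (adjusted p = 0.0108). The metalloreductase Steap4 fell from 130 ± 28.3 to 55.9 ± 27.2 CPM (adjusted p = 0.0422). Lcn2, an iron-sequestering protein gene that also stands in the list of neutrophil markers, fell from 91.0 ± 56.8 to 20.8 ± 12.6 CPM (adjusted p = 0.0315). The calls of Steap4, Lcn2 and Orm1 were lost in 9, 8 and 3 of 24 alternative settings, with adjusted p up to 0.173, 0.0992 and 0.0565. Of 11 measured neutrophil and monocyte markers 2 fell and 0 rose (6 and 0 adjusted over the list alone), with a median of -2.64 and a camera adjusted p of 4.49e-05 (adjusted p = 0.439 with an estimated correlation). The median ran from -3.17 to -1.35 across settings. The mean log2 level of these markers was highest in SD_403 (3.61) and SD_646 (3.20), lay between -0.27 and 1.14 in the other standard diet mice, and between -1.20 and -0.19 on the Longevity diet, so that SD_502 overlapped that diet. S100a8, an abundant neutrophil protein gene, fell from 13.1 ± 15.5 to 0.343 ± 0.212 CPM (adjusted p = 0.0456), a call lost in 16 of 23 alternative settings with adjusted p up to 0.313 and log2 changes of -4.43 to -2.46. Its partner S100a9 had a log2 difference of -2.64 (adjusted p = 0.131).

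Extracellular matrix genes and markers of stellate and sinusoidal endothelial cells stood lower together. Of 22 measured matrix genes 2 fell and 0 rose (13 and 0 adjusted over the list alone), with a median log2 change of -0.80 and a camera adjusted p of 1.36e-07 (adjusted p = 0.363 with an estimated correlation). The collagen gene Col5a1 fell from 11.1 ± 1.93 to 3.92 ± 1.08 CPM (adjusted p = 0.00974) and the matrix protein gene Postn from 11.8 ± 2.48 to 5.34 ± 1.06 CPM (adjusted p = 0.0275, lost in 11 of 23 alternative settings), while Col1a2 was at 14.6 ± 6.64 and 5.50 ± 1.93 CPM (adjusted p = 0.0630). Of 16 measured stellate cell and fibroblast markers 1 fell and 0 rose (4 and 0 adjusted over the list alone), with a median of -0.59 and a camera adjusted p of 0.000397 (adjusted p = 0.160 with an estimated correlation). The growth factor receptor gene Pdgfrb fell from 10.8 ± 1.97 to 4.35 ± 1.66 CPM (adjusted p = 0.0290, lost in 7 of 23 alternative settings), and the proteoglycan gene Dcn was at 216 ± 44.7 and 123 ± 26.6 CPM (adjusted p = 0.0680). Among 16 sinusoidal endothelial markers 0 passed over all genes and 8 fell adjusted over the list alone, with a median of -0.70 and a camera adjusted p of 5.40e-06 (adjusted p = 0.439 with an estimated correlation). The endothelial receptor genes Fcgr2b and Stab2 had log2 differences of -1.06 (adjusted p = 0.0506) and -1.12 (adjusted p = 0.102). The mean log2 level of the endothelial markers was 3.55 in LD_406 and 3.36 in LD_515, 4.17 to 4.43 in the other mice of that diet and 4.53 to 4.92 on the standard diet.

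Markers of immune cells and interferon-stimulated genes gave weaker calls, with 0 members past the threshold over all genes. Kupffer cell markers had a median log2 change of -0.61 over 17 genes, of which 1 fell adjusted over the list alone (camera adjusted p = 0.0225, adjusted p = 0.749 with an estimated correlation). The macrophage gene Mpeg1 was at 105 ± 26.2 and 44.4 ± 29.8 CPM (adjusted p = 0.0685). B cell and plasma cell markers had a median of -1.25 over 16 genes and 0 members past the threshold adjusted over the list alone (camera adjusted p = 0.0433, adjusted p = 0.650 with an estimated correlation), with the plasma cell gene Mzb1 at 2.45 ± 0.956 and 0.874 ± 1.32 CPM (adjusted p = 0.121). Interferon-stimulated genes had a median of -0.58 over 27 genes and 0 past the threshold adjusted over the list alone (camera adjusted p = 0.0433, adjusted p = 0.831 with an estimated correlation). The B cell, interferon and Kupffer calls were lost in 9, 6 and 5 of 24 alternative settings, with adjusted p up to 0.216, 0.322 and 0.234. The interferon-stimulated gene with the smallest p, Usp18, stood in the other direction at 0.90 (adjusted p = 0.170). T and NK cell markers (camera adjusted p = 0.536), MHC class II genes (0.166) and cholangiocyte markers (0.836) were not called, although MHC class II genes were in 6 of 24 alternative settings and T and NK cell markers in 2 of 23. Among the mice on the Longevity diet LD_406 and LD_515 were lowest in the mean log2 level of Kupffer cell markers (3.23 and 3.44), of B cell markers (0.69 and 0.81) and of T and NK cell markers (-1.03 and -1.59), and in the score of MHC class II genes (-1.12 and -1.95). LD_405 (4.60) and LD_442 (4.76) lay above the standard diet mean of Kupffer cell markers (4.57), and LD_515 was lowest in the score of interferon-stimulated genes (-1.19).

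Mup1, a major urinary protein gene, fell from 40.8 ± 37.8 to 0.284 ± 0.211 CPM (log2 change -6.28, adjusted p = 0.00160), Mup9 from 78.7 ± 84.7 to 0.310 ± 0.252 CPM (adjusted p = 0.0181) and Mup22 from 31.9 ± 22.7 to 1.22 ± 1.27 CPM (adjusted p = 0.0114). Mup10 fell from 4.04 ± 3.35 CPM to values under the floor of 3 reads in all 5 mice on the Longevity diet (adjusted p = 0.0118). Mup genes are nearly identical in sequence, so reads can be shared among them. The estrogen sulfotransferase Sult1e1 fell from 30.2 ± 37.7 to 0.314 ± 0.255 CPM (log2 change -5.73, adjusted p = 0.00283), and Sult5a1 from 16.5 ± 18.1 to 0.392 ± 0.341 CPM (adjusted p = 0.00360). Longevity diet values this close to the added 0.1 CPM make the log2 changes depend on it, and across settings Mup1 ran from -6.86 to -4.44 and Sult1e1 from -6.65 to -3.89, both losing the call with voom (adjusted p = 0.122 and 0.113). These ranges were -7.44 to -4.68 for Mup9, -5.30 to -3.61 for Mup22, -6.95 to -2.00 for Mup10 and -5.84 to -3.24 for Sult5a1. Mup9 lost the call in 4 and Mup22 in 2 of 24 settings, with adjusted p up to 0.379 and 0.102, and Mup10 and Sult5a1 each in 1 of 23, with adjusted p up to 0.208 and 0.0841. The neurotrophin receptor gene Ntrk2 fell from 83.4 ± 25.3 to 2.72 ± 3.14 CPM (adjusted p = 0.00360), the protease inhibitor gene Serpinb1a from 71.9 ± 42.5 to 4.57 ± 4.31 CPM (adjusted p = 0.00869), and Mmd2 from 35.7 ± 19.9 to 2.48 ± 2.05 CPM (adjusted p = 0.00621). Their log2 changes ran from -6.42 to -4.88, -4.99 to -3.82 and -4.54 to -3.45 across settings.

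The secreted proteoglycan gene Tsku rose from 10.4 ± 6.17 to 85.2 ± 32.1 CPM (log2 change 3.10, adjusted p = 0.00360) and the glypican gene Gpc1 from 3.77 ± 2.87 to 28.6 ± 8.51 CPM (log2 change 3.10, adjusted p = 0.00349). The magnesium channel gene Trpm6 rose from 0.339 ± 0.369 to 5.56 ± 2.10 CPM (adjusted p = 0.00421), and the adrenergic receptor gene Adra2a from 0.173 ± 0.111 to 3.93 ± 2.95 CPM (adjusted p = 0.00887). Pnldc1, a ribonuclease gene, rose from 0.454 ± 0.539 to 5.18 ± 3.48 CPM (adjusted p = 0.0383), a call lost in 11 of 23 alternative settings. Cacng1, a calcium channel subunit gene, was at 0 CPM in all standard diet mice but SD_502, which had 0.175 CPM, and rose to 2.05 ± 0.803 CPM (adjusted p = 0.00539). The log2 changes of genes this low depend on the added 0.1 CPM, and across settings they ran from 2.27 to 4.73 for Trpm6, 1.88 to 4.74 for Adra2a, 1.93 to 5.08 for Pnldc1 and 1.52 to 6.75 for Cacng1.

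The growth hormone and IGF-1 axis was not called as a list (camera adjusted p = 0.0760), although 2 of 15 measured members fell and 0 rose (3 fell and 1 rose adjusted over the list alone). The list was called in 5 of 24 alternative settings. The growth hormone receptor gene Ghr fell from 431 ± 59.3 to 223 ± 44.3 CPM (adjusted p = 0.0178, lost in 3 of 24 alternative settings) and the IGF carrier gene Igfbp3 from 42.6 ± 23.5 to 9.54 ± 1.91 CPM (adjusted p = 0.0122). Igf1 itself was at 578 ± 75.5 and 376 ± 41.2 CPM (adjusted p = 0.0634), with no overlap between the diets. Sex-biased liver genes went both ways. Among 14 male-biased genes 2 rose and 1 fell (2 and 3 adjusted over the list alone, camera adjusted p = 0.386), namely Cyp2d9 (log2 change 2.06, adjusted p = 0.0259), Gstp1 (1.04, adjusted p = 0.0449) and Mup1. Among 19 female-biased genes 1 rose and 1 fell (2 and 4 adjusted over the list alone, camera adjusted p = 0.772), namely Cyp2a4, from 1321 ± 338 to 2937 ± 460 CPM (adjusted p = 0.0117), and Cyp3a41a, from 2233 ± 720 to 703 ± 319 CPM (adjusted p = 0.0298). The phenobarbital-inducible Cyp2b10 fell from 51.7 ± 7.48 to 10.1 ± 5.66 CPM (adjusted p = 0.00283). In the list of drug-metabolising cytochromes, Cyp2a4 was the 1 of 22 that rose and Cyp2b10 the 1 that fell (4 and 1 adjusted over the list alone, median 0.12, camera adjusted p = 0.0469, adjusted p = 0.581 with an estimated correlation). That camera call was lost in 12 of 24 alternative settings, and the median turned sign, running from -0.105 to 0.305 across settings. The calls of Gstp1, Cyp3a41a and Cyp2d9 were lost in 13, 7 and 6 of 24 settings, with adjusted p of Gstp1 up to 0.172 and of Cyp2d9 up to 0.0992. Reads of Cyp2d9, Gstp1, Cyp2a4 and Cyp3a41a can be shared with close paralogs.

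Of 20 circadian clock genes 2 rose and 0 fell (3 and 2 adjusted over the list alone), and the list was not called (camera adjusted p = 0.0935), although it was in 3 of 24 alternative settings. Usp2, a clock-controlled ubiquitin protease, rose from 4.36 ± 2.51 to 39.8 ± 25.0 CPM (adjusted p = 0.0163, lost in 3 of 24 alternative settings) and the transcriptional repressor Ciart from 1.10 ± 0.987 to 9.04 ± 7.40 CPM (adjusted p = 0.0449), the latter call being lost in 11 of 23 alternative settings, with log2 changes of 2.02 to 3.30. Arntl, which encodes the core activator BMAL1, was at 7.33 ± 8.04 and 0.930 ± 0.666 CPM (adjusted p = 0.0904), and the repressor Nfil3 at 24.8 ± 21.1 and 6.88 ± 4.01 CPM (adjusted p = 0.0949). The list of autophagy and lysosome genes was not called (camera adjusted p = 0.848), with 1 of 24 risen and 2 fallen (1 and 3 adjusted over the list alone). Map1lc3a, an autophagosome protein gene, rose by 1.10 (adjusted p = 0.0289), and the lysosomal protease gene Ctsb changed by -0.70 (adjusted p = 0.0469) on the log2 scale. The calls of Ctsb and Map1lc3a were lost in 15 and 9 of 24 alternative settings, with adjusted p up to 0.127 and 0.126.

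Mitochondrially encoded mRNAs had a median log2 change of -0.94 over 13 genes, with 0 past the threshold over all genes and 9 fallen adjusted over the list alone (camera adjusted p = 4.13e-06, adjusted p = 0.549 with an estimated correlation). The respiratory chain genes mt-Nd4 and mt-Co1 stood at -1.08 (adjusted p = 0.0982) and -0.94 (adjusted p = 0.103). Mitochondrial mRNA made up 9.58 ± 2.55% of counts on the standard diet and 5.27 ± 1.57% on the Longevity diet (n = 5 each, exact permutation p = 0.0238), and albumin mRNA 7.91 ± 1.98% and 12.5 ± 2.07% (n = 5 each, exact permutation p = 0.0159). In SD_502 mitochondrial mRNA was 5.06%, within the Longevity diet values of 3.14 to 7.01%. The other standard diet mice had 10.2 to 11.3%. Cytosolic ribosomal protein genes had a median of 0.38 over 36 genes with 0 past the threshold, also adjusted over the list alone (camera adjusted p = 1.36e-07, adjusted p = 0.558 with an estimated correlation), and Rpl3 stood at 0.96 (adjusted p = 0.133). The score of this list was lowest in SD_502 (-1.53) and highest in LD_405 (1.32), with an exact permutation p of 0.167 between the diets, and the median was 0.22 without either of these mice in turn. The tenth of genes with the shortest transcripts deviated by -0.61 in SD_502 and 0.69 in LD_405 from the other mice of their diets. Nuclear genes of oxidative phosphorylation had a median of 0.09 over 27 genes, with 0 past the threshold, also adjusted over the list alone (camera adjusted p = 0.0433, adjusted p = 0.831 with an estimated correlation), and Ndufv1 stood at 0.50 (adjusted p = 0.227). The oxidative phosphorylation call was lost in 10 of 24 alternative settings.

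Of the 43 lists tested, 18 were called by camera, 8 towards higher and 10 towards lower values, and 25 were not called (adjusted p 0.0760 to 0.848). Of the 18 calls 0 held with an estimated correlation (adjusted p = 0.0872 to 0.831), and 0 held by the exact permutation test of the list score per mouse after adjustment (lowest adjusted p = 0.0569), although 11 of the 18 had an unadjusted p under 0.05. The lists not called and not yet described include proliferation (adjusted p = 0.555), senescence (0.568), heat shock proteins (0.848), endoplasmic reticulum chaperones (0.250), immediate early genes (0.848), lipoproteins (0.320), gluconeogenesis (0.434), bile acid synthesis (0.772), and sirtuins and nutrient sensing (0.379). Gluconeogenesis was called in 2 of 24 alternative settings, and endoplasmic reticulum chaperones and periportal markers in 1 each. Periportal and pericentral hepatocyte markers had adjusted p of 0.243 and 0.848, and erythroid and adipocyte markers 0.828 and 0.836. In periportal markers 1 member fell, which was Gls2, and in antioxidant genes (adjusted p = 0.555) 1 rose, which was Gstp1. In the tumour-associated and fetal genes (adjusted p = 0.386) Cyp2b10 and Lcn2 fell. Median, mean and test differed in sign for the lists of sirtuins, gluconeogenesis, proliferation, antioxidant, female-biased, bile acid, erythroid, cholangiocyte, adipocyte, pericentral, autophagy and heat shock genes. The pancreatic, mesothelial and sex chromosome lists had fewer than 3 measured members and were not tested.

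The first principal component held 31.2% of the variance and differed between the diets (n = 5 each, exact permutation p = 0.0317), and the second held 21.7% (n = 5 each, exact permutation p = 0.0635). On the first component LD_442 (-12.8) and LD_513 (-10.9) lay within the standard diet scores of -43.9 to -8.52. The test of that component was not repeated without LD_405. LD_405 stood apart from the other mice on the first component, with a score of 96.2 where the next was 38.2 in LD_406. On the second, its score of 36.5 lay apart from its own diet but within the standard diet scores of -18.7 to 41.9. The number of changed genes ranged from 97 without SD_403 to 378 without LD_405, and 25 of 59 changed named genes other than Fgf21 lost the call with at least 1 mouse left out. Named genes that changed and for which no lost setting is given here passed in all or all but 1 of their settings. With the leading digit of the mouse number as a covariate, whose meaning the labels do not give, 98 genes changed and 26 of the 59 named calls were lost, the most in any setting, and without LD_405 and SD_403 together, an alternative added after seeing the data, 175 genes changed, 76 higher and 99 lower.

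**Figure D4:**
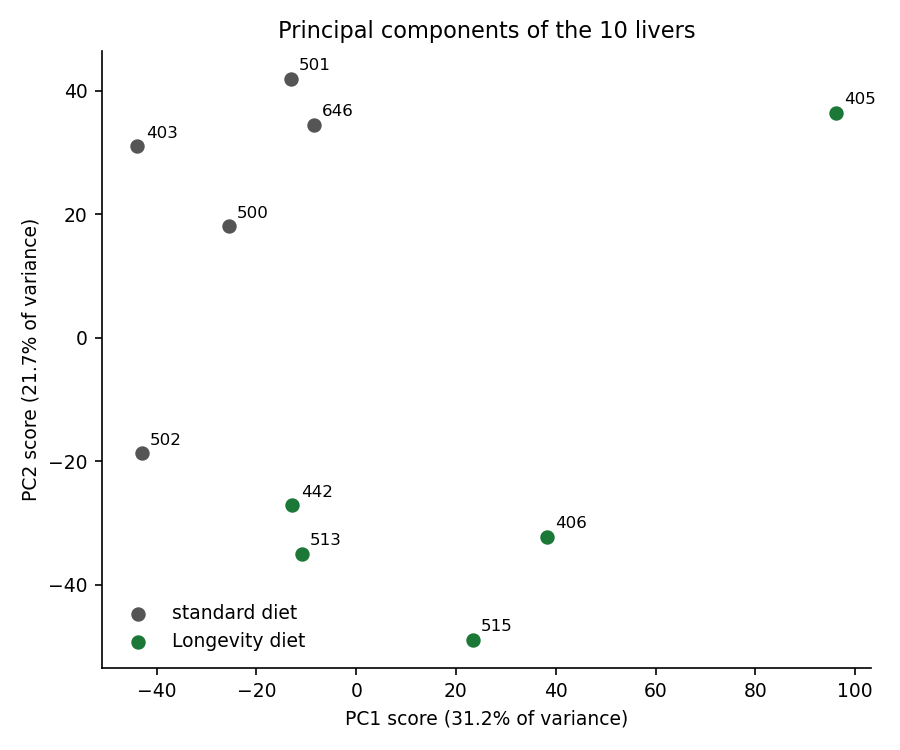
Scores of the 10 mice on the first and second principal components of log2 expression, 1 point per mouse, with the axes giving 31.2% and 21.7% of the variance. LD_405 lies at 96.2 and 36.5, away from the other mice of its diet.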

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

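The tests of library depth, of non-hepatocyte markers and of clock genes in this part were chosen only after the results they concern had been seen. That of chance splits was written beforehand. Those of transcript length and GC and of tissue taken with the liver were written before they were run. They name LD_405, however, so its standing apart had been seen by then. In 226 groups of 5 values, 10 held a value whose gap to its nearest neighbour exceeded 0.71 of the range of the group, and chance alone gives about 1 in 20. Of 100 splits of the 10 mice into 5 and 5, drawn from the 126 possible, 1, the real split, gave as many as 249 changed genes. The highest of the others gave 3, so a random split of these mice would rarely give such a number. The splits cannot tell diet from other differences between the groups, such as that in depth.

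Mouse LD_405 of the Longevity diet scored 36.5 on the second principal component, where the other 4 mice of its diet lay between -48.9 and -27.1. Low depth is argued against by its 39.1 M reads, where the highest of the other 4 was 34.6 M. An effect of its higher depth was not tested. Transcript length and GC content explained 30.3% of the variance of its deviations from the others of its diet, more than in any other library (the next was 19.7% in LD_513), and its longest transcripts were lower by a median of -1.11, so a bias of RNA quality or library preparation is a candidate explanation. Markers of tissue taken with the liver leave the matter open, since the median deviation of 2.38 that met the bound rests on 2 pancreatic genes, Cela2a and Pnliprp1, at 1.84 and 0.179 CPM in this mouse. A need for at least 3 genes was added after that value was seen, and the other marker lists reached at most 0.55. The median over all 21 markers was 0.54 (SD 1.29), under the bound of 1 by less than that spread. That bound was set before the test was run. No biological explanation was tested.

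Markers of 5 of 7 cell types other than hepatocytes were called lower as lists by camera on the Longevity diet. Per mouse, the exact permutation p was 0.00794 for sinusoidal endothelial and for stellate markers, 0.0238 for neutrophil and monocyte, 0.135 for Kupffer cell, 0.111 for B cell, 0.508 for T and NK cell and 0.714 for cholangiocyte markers. Scaling is argued against as the whole cause of the lower matrix, stellate and endothelial levels. Their mean log2 changes of -0.87, -0.61 and -0.76 were -0.76, -0.50 and -0.65 after median-of-ratios scaling (SE 0.23, 0.14 and 0.24, exact permutation p at most 0.0238). With length and GC slopes removed, their camera adjusted p at the preset correlation stayed at or under 0.000114. Their medians ran from -0.946 to -0.587, -0.723 to -0.483 and -0.825 to -0.552 across all 24 settings, that one among them. No test per mouse was run with the slopes removed, so a length or GC bias is not excluded as part of the cause. A like fall of all 7 cell types stays open, because their changes differed at an exact permutation p of 0.0476 with mice permuted, but of 0.111 to 0.246 without SD_403, without SD_646 or without any single mouse of the Longevity diet. For the 6 lists other than neutrophils that exact permutation p was 0.524, so a lower share of these cells together, lower expression within them, and an effect of diet stay open as well, and 0 of these camera calls held with an estimated correlation.

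Nfil3 in mouse SD_403 was 5.96 on the scale of log2(CPM + 0.1), against 3.68 to 4.33 in the others of its diet. Clock genes with an evening peak were above 0 in 10 of 10 cases (median log2 change 0.78), and 1 of 5 genes of the Bmal1 arm was (median -1.76). These arms held 15 of the 20 listed clock genes, and over all 20 the log2 change was above 0 in 13 and below 0 in 7. The listed genes set aside went both ways, and were placed in the evening arm only for the test with all 20. The difference between the arms per mouse gave an exact permutation p of 0.0317, or 0.0476 with all 20 listed clock genes assigned. By that test the evening arm alone gave 0.0635 and the Bmal1 arm alone 0.0952. The difference was lowest in SD_403 (-3.17), while SD_646 (0.753) lay within the Longevity diet values of 0.157 to 1.37 and SD_502 (0.121) just below them. A shift in clock phase is a candidate explanation, though the arms were assigned after single gene changes had been seen. Leaving out LD_405, LD_406 or LD_442 gave an exact permutation p of the difference of 0.0714, 0.0714 and 0.0635, and every other single mouse left out gave 0.0476 or less. With 0 of 10 samples carrying a time of day, an effect of diet on the clock and a difference in collection time cannot be told apart.

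Mitochondrial mRNA was 5.06% of counts in mouse SD_502, against 10.2 to 11.3% in the others of its diet. The score of the mitochondrial mRNA list was -0.721 in that mouse, against 0.870 to 0.976, and mt-Co1 was 14.4 on the log2 scale, against 15.4 to 15.6. Cacng1 was -1.86 on that scale in SD_502, while the other 4 standard diet mice were at -3.32, which is 0 CPM. Albumin was 16.1% of counts in mouse LD_515, against 11.1 to 12.3% in the others. The 18S rRNA gene took 5.65% of counts in mouse LD_513, against 0.507 to 1.22% in the others. In mouse LD_405, Asns was -0.49 on the same log2 scale, against 2.83 to 3.74 in the others of its diet, and Otc was 7.48, against 7.70 to 7.79.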

How the results depend on the processing

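The alternatives chosen only after seeing the data were the voom weights, scaling without the most abundant genes, removal of length and GC slopes, and leaving out LD_405 and SD_403 together. All 249 changed genes that an alternative tested kept their sign in it. Fgf21 passed in all 24 settings, and its log2 change with single mice left out was 3.00 to 3.61. The number of changed genes was 541 (202 higher, 339 lower) at an adjusted p of 0.1, 805 (329, 476) with library weights, 98 (28, 70) with the leading digit of the mouse number, of unknown meaning, as covariate and 479 (168, 311) with length and GC slopes removed. Genes higher were 154 with median-of-ratios scaling and 151 with quantile normalization, and genes lower in the Longevity diet were 105 with a 10 CPM filter, which tested fewer genes, and 99 without LD_405 and SD_403. Leaving out single mice gave 97 to 378 genes, 31 to 151 higher and 58 to 227 lower. It gave 97 without SD_403, 108 without SD_500 and 147 without SD_501. It gave 378 without LD_405, 98 without LD_406 and 112 without LD_515. Of the 43 lists, 0 were called with an estimated correlation, 6 by fry in 1 direction, 25 by fry in mixed directions and 0 by permutation of the score per mouse after adjustment. Camera at the preset correlation called 13 to 19 lists with single mice left out, and 13 of its 18 calls held in every setting that tested them at that correlation. Gcgr reversed to -0.000138 with quantile normalization, -0.0895 with library weights, -0.0359 with the covariate, -0.137 with the slopes removed and -0.132 without LD_405 and SD_403, and Fgfr2 to -0.0234 with the covariate. With single mice left out Gcgr ranged from -0.0968 to 0.127 and Fgfr2 from -0.0922 to 0.249, and neither passed in any of these. Of 59 other named genes that changed, 19 passed in every setting, 25 lost the call with at least 1 mouse left out, and 0 reversed. Of the 26 that had not passed, 15 did in at least 1 setting. For principal component 2, the mean score was 21.4 on the standard diet and -21.4 on the Longevity diet (exact permutation p = 0.0635). With the 500 most variable genes, the difference between diets in the mean score was 2.74 on component 2 (exact permutation p = 0.857). On component 1 of those genes it was 41.7 (exact permutation p = 0.00794), where all tested genes gave a p of 0.0317 by that test. Components of different gene sets are different axes on different scales, so the sizes of these scores cannot be compared. Where fewer mice or genes do not account for a difference, the cause was not tested. Equal column totals moved nothing. DESeq2 and edgeR on recovered reads were not run, because only 84.6% to 87.9% of low values were whole reads. At 24.7 to 45.7 M reads, genes near 0.1 CPM rest on few reads.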

Other observations

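The search for clusters of changed genes in the genome was chosen only after the changed genes had been seen, and the genes in this part lie outside the rule for named genes and were chosen after their values were seen. C9, a component of the membrane attack complex of complement, had the smallest p of all genes, falling from 237 ± 60.1 to 38.5 ± 12.0 CPM (log2 change -2.63, adjusted p = 0.000585). The estrogen receptor gene Esr1 fell from 35.9 ± 6.12 to 14.6 ± 1.61 CPM (adjusted p = 0.00442). The oxysterol hydroxylase gene Cyp39a1 rose from 17.0 ± 6.72 to 85.8 ± 34.7 CPM (adjusted p = 0.00605) and the bile acid transporter gene Slc10a2 fell from 29.7 ± 15.5 to 4.04 ± 4.48 CPM (adjusted p = 0.0114), while the fixed list of bile acid synthesis and transport had 0 of 22 members past the threshold (camera adjusted p = 0.772). Hamp2, a relative of the hepcidin gene, did not pass despite a wide difference, at 2899 ± 2131 and 85.1 ± 128 CPM (log2 difference -6.90, SE 1.56, adjusted p = 0.0649). Its standard diet values lay between 722 and 6212 CPM and its Longevity diet values between 0.423 and 309 CPM. Xist was at 849 ± 109 and 437 ± 192 CPM (adjusted p = 0.0852).

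HET3 mice differ in genotype, so chance sharing of haplotypes within a diet is a hypothesis for part of the changed genes, and such genes might then lie close together. There were 56 pairs of changed genes within 1 Mb, leaving out pairs with the same symbol root, where 2000 random sets matched on expression gave a median of 52 (permutation p = 0.323). No excess was found, but with no genotypes and no estimate of the excess to be expected, a contribution of haplotypes stays open. Of 87 named genes, 21 overlap another gene in the table and 19 of these overlap a gene on the other strand, among them Gpc1, Cyp51, Gls2, Ctsb, Gss and Rpl3, and their counts depend on the library strandedness, which is not stated.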
